A study of Mus musculus with 16 samples.

How the data were processed

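The series holds 16 RNA-seq libraries of mice of the Collaborative Cross strain CC037, a recombinant inbred line from a multi-parent mouse population. The labels name total RNA, extraction with RNeasy kits and libraries made by a service company. Groups were taken from the genotype and tissue labels: 4 colon WT, 4 colon HO, 5 lung WT and 3 lung HO libraries, where WT carries wild-type Cftr and HO the F508 mutation of Cftr. The number in each title was read as the animal number. It occurs in 10 different forms, and 6 of them occur in both tissues. Replicates are named by this number. Nothing in the labels says how the animals were housed, their sex or when the libraries were sequenced.

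The deposited table holds normalised values on a signal scale, made by the authors; the submitters' processing notes name mm10 and DESeq2. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. The table has 42110 lines, of which 1 has no gene name. That line held between 0 and 4 reads per library, at most 0.000164% of a library's total, and was left out. In 13 libraries the smallest value was exactly 1, every value was whole and all but at most 9 values per library were odd, so that a value equals 2 times the reads plus 1. In lung WT replicates 5839 and 5842 the same held for multiples of 1.06 and 1.07. In lung WT replicate 6752 the multiples of 1.18 were both odd and even, so that a value equals the reads plus 1, on a scale smaller by a factor of 2 than that of the other libraries. In that library 99.99% of the values were whole multiples within 0.01, and 5 were not. In the other libraries 100% were whole. Reads recovered in this way numbered between 1694925 and 3492042 per library, which sets the depth behind every value. Whether PCR duplicates were removed is not given either, and counts of reads cover counting error only.

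The planned test assumed that the deposited values had been brought to a common depth. A smallest value of exactly 1 in 13 libraries of unequal totals shows that those had not been. The main test was therefore run on values rescaled within each tissue by the median of ratios to the geometric mean of that tissue, over 16170 features for colon and 14031 for lung with reads in every library of the tissue. The factors ran from 0.742 to 1.18 in colon and from 0.432 to 1.41 in lung. This rescaling had been listed as an alternative before the data were examined. It was made the main setting only after the numbers of called features under both scales had been seen, and it gave more of them. The numbers on the deposited scale are printed beside those on the rescaled scale for this reason.

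Log2 of the rescaled value plus 1 was tested with limma 3.58.1 (lmFit and eBayes with trend and robust, two-sided) in R 4.3.3. Features with a deposited value of at least 10 in at least 3 libraries of the tissue were tested, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. A fold change is therefore on the log2(value + 1) scale, where the added 1 understates the change of low features. Rescaling also divides the value of a feature without reads, so that the floor differs between libraries. It was highest in lung WT replicate 6752, with a smallest value of 1.18 and a factor of 0.432. Lung HO libraries had smallest values of 1 and factors from 1.13 to 1.41. Features near the floor can therefore appear lower in HO labelled lung, and in the genotype by tissue term. Colon and lung were fitted separately. The genotype by tissue term, the HO effect in lung minus that in colon, was fitted on all 16 libraries. Of 52 gene lists fixed before the data were examined, those with at least 4 tested members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Quasi-likelihood tests of edgeR 4.0.16 and Wald tests of DESeq2 1.42.0 were run on the recovered reads as alternatives.

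Many gene names in the table did not carry the reads that the gene should have. Names were therefore checked by position, with a procedure devised after the data had been seen. Of the 42109 names, 38794 occur once in the GENCODE M21 annotation of GRCm38 (mm10). For 1872 genes that nearly every tissue uses, such as subunits of the proteasome and of the respiratory chain, the mean of the recovered reads over all 16 libraries was set against a minimum of 50. On each of 20 chromosomes at most 1 break was placed. Before it, such genes were taken to reach the minimum with a probability of 0.9, or 0.65 for families used less evenly, and after it as often as over all chromosomes. The stretch before the break was kept where its posterior probability was at least 0.99, the log likelihood ratio at least 3 and the number of these genes at least 3. The minimum and the probabilities were set after values on chromosomes 4 and 6 had been seen. Scans for shifted positions, hidden Markov models and iterated fits were tried on the same means before this and dropped. The scans showed no clear shift, and the fits drifted or picked clusters of olfactory receptor genes. Their stretches ended elsewhere, mostly farther along. Genotype and tissue played no part in any of them. The 990 names inside the stretches, 2.35% of all names, are called position-checked below. They lie on chromosome 2 up to 10.1 Mb, on chromosome 4 up to 49.6 Mb, on chromosome 6 up to 30.2 Mb and on chromosome 18 up to 6.02 Mb. These stretches hold 4, 36, 15 and 3 of the genes used for the check, so that names on chromosomes 2 and 18 rest on few of them. Coordinates are those of GENCODE M21 on GRCm38.

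Genes to be named were set by a rule fixed before the data were examined: Cftr first; per tissue the 12 largest rises and the 12 largest falls past the threshold whose groups do not overlap, with a mean of at least 50 in the higher group and a symbol that is not a predicted model; with fewer than 5 in a direction, the smallest-p genes up to 10 named as not passing; up to 4 members of a list that passed or had at least 2 members past the threshold; and for the genotype by tissue term the 6 smallest-p genes per side. The rule was applied to all features, and once more among position-checked names, which is a departure made after the data had been seen. Genes not passing, list members and genes of the genotype by tissue term were taken from position-checked names alone. Called features with other names are reported as features deposited under that name, since which transcript they measure is not established. A called feature that the symbol rule excludes is named where it is said to have been chosen after its values were seen.

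Alternatives covered the pseudocount (0.5 and 5), the filter (none, or 50), the scaling (deposited, equal totals, quantile), limma without trend and robust estimation, library weights, a threshold of 0.1, the leading digit of the animal number and the mean of 4 features deposited under Y-linked names as covariates, a fit of all libraries with and without the animal number as a block, and leaving out each replicate in turn. Limiting the tests and lists to position-checked names was added after the data had been seen. Libraries of the same animal number deviated together only weakly: the correlation of their deviations from the group means ran from -0.0945 to 0.156 over 6 pairs, with 1 above 0.1. Within a tissue each animal number occurs once, so that no pair enters the HO against WT tests. For the genotype by tissue term the block gave a consensus correlation of 0.0284.

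The procedure was tested on simulated data, in which 200 features were changed by known folds among reads drawn from the real means, library sizes and dispersions. Of the features changed 4-fold, 93.8% were called among 15692 features for colon, 88.2% among 13805 for lung, and 78.0% among 12839 for the genotype by tissue term. Of those changed 2-fold, 45.7%, 31.9% and 28.9% were called. Of unchanged features, 0.0581%, 0.0441% and 0.0396% were called. Scripts used Python 3.11.15, pandas, scipy and matplotlib.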

Results

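RNA was measured by sequencing in colon and lung of CC037 mice with wild-type Cftr (WT) or with the F508 mutation of Cftr (HO). The series title names the gut-lung axis in cystic fibrosis as its subject. There were 4 colon WT, 4 colon HO, 5 lung WT and 3 lung HO libraries. Recovered reads numbered from 2429899 to 3492042 per library labelled colon and from 1694925 to 3437143 per library labelled lung, which is shallow for genes of low abundance. Of 42110 features in the table, 13132 had no read in any library. Values below are deposited values rescaled for depth within each tissue, and errors are SD between replicates.

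Several abundant genes lacked reads under their own names. Features named Actb, Lyz2, Acta2 and Hba-a1, for a cytoskeletal actin, a lysozyme of myeloid cells, a smooth muscle actin and a globin, lay near the floor in the libraries, whereas that named Frmd8 in every library, and that named Nprl3 in libraries labelled colon, ranked high. Not every such name lay at the floor: that of Eef2, a factor of protein synthesis, had deposited values of 117 to 297. Of the genes used to check names, 82.8% (48 of 58) had at least 50 mean reads inside the position-checked stretches against 37.3% (677 of 1814) outside them. Inside and outside were chosen on these same genes. When the stretches were refitted on every other gene and scored on the rest, the figures were 77.8% (21 of 27) and 38.2% (704 of 1845). The refitted stretches were shorter, with 27 scored genes inside against 58 in those used here. Of other named protein-coding genes, which set nothing, 67.8% and 32.1% passed. Cftr and its neighbours lie in a position-checked stretch. For features elsewhere the deposited name is printed, but which transcript was measured is not established.

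**Figure D1:**
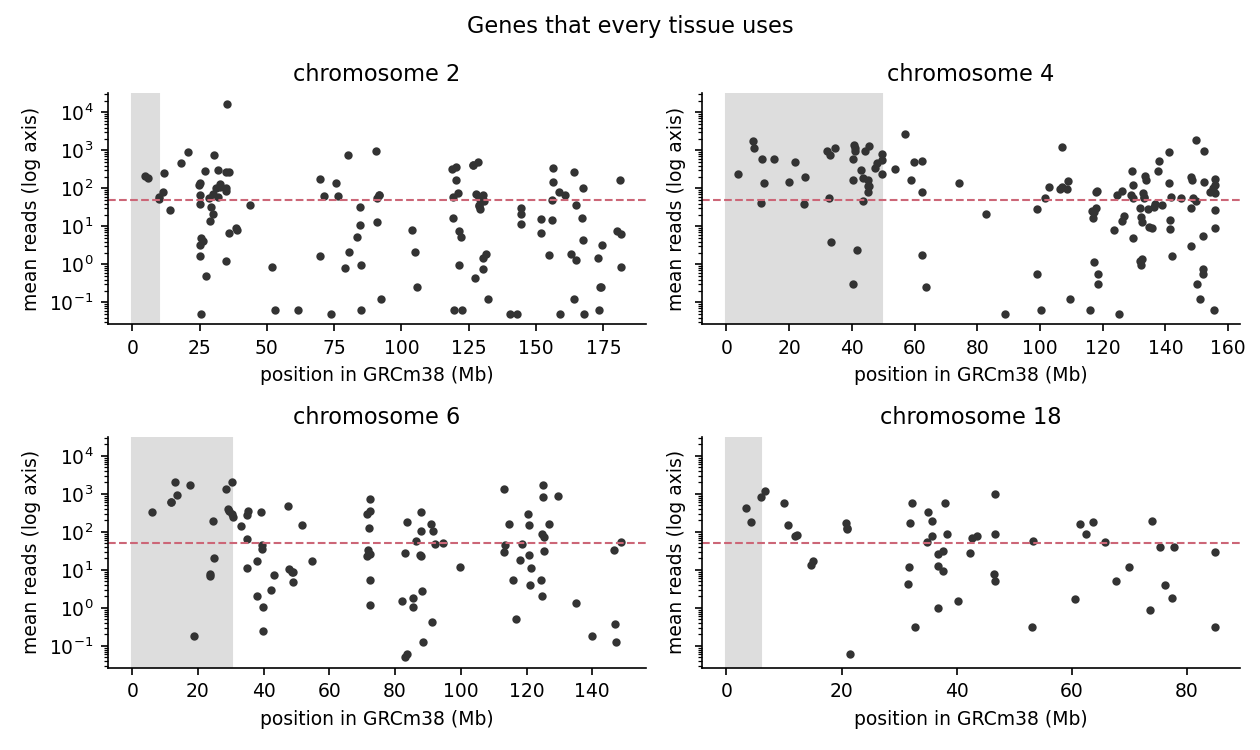
Mean recovered reads over all 16 libraries (log axis, values under 0.05 drawn at 0.05) of the genes used to check names, by position on chromosomes 2, 4, 6 and 18. Grey marks the position-checked stretch and the dashed line 50 reads; inside the stretches 82.8% of these genes reached that line.

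The tissue labels were compared with markers from the fixed lists whose names are position-checked. Cdh17, a cadherin of intestinal epithelium, Spink4, a goblet cell peptide, and Tac1, the substance P precursor of enteric neurons, are markers of gut. Cav1, of alveolar type 1 cells, Atp6v0d2, of alveolar macrophages, and 1110017D15Rik, of ciliated cells, are markers of lung, although Cav1 is used by several other cell types. All 6 separated the tissues against their labels, with no overlap between 8 and 8 libraries and an exact two-sided permutation p of 0.000155 each, the smallest that 8 against 8 can give and unchanged by adjustment over the 6. Cdh17 averaged 5.09 ± 1.76 per 1000000 of the deposited total (SD, n = 8) in libraries labelled colon and 2559 ± 430.2 (n = 8) in those labelled lung. For Spink4 the means were 2.07 ± 0.451 and 552 ± 228. Cav1 averaged 5061 ± 734 in libraries labelled colon and 516 ± 108 in those labelled lung. Both tissues are therefore named by their labels throughout, as "labelled colon" and "labelled lung", and every statement on a tissue below refers to the label alone.

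**Figure D2:**
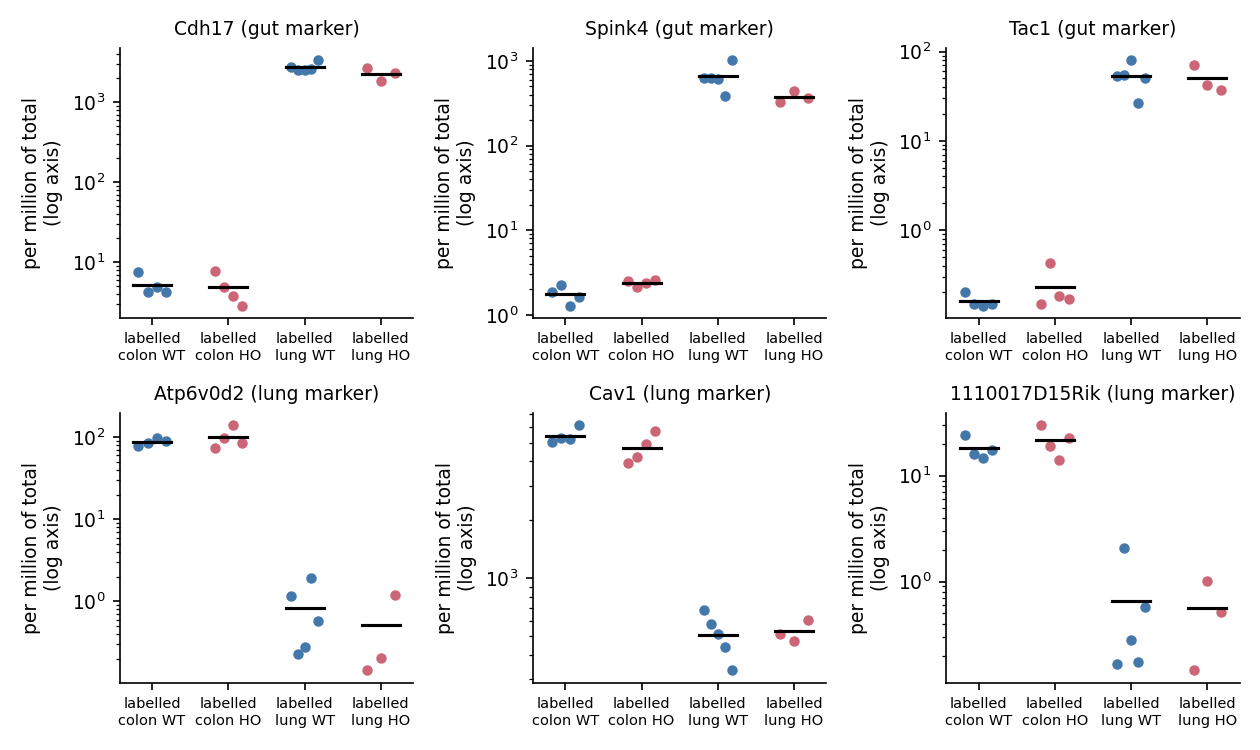
Markers of gut and of lung per 1000000 of the deposited total (log axis) in each library, by tissue label. All 6 markers lay on the side opposite to their label in 8 of 8 libraries per tissue.

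The first comparison asked which transcripts differ between HO and WT in libraries labelled colon. Cftr, the chloride and bicarbonate channel of epithelia that carries the mutation, fell in HO. Its neighbours on chromosome 6, Cttnbp2, a partner of cortactin, and Aass, which starts the breakdown of lysine, fell as well. Car8, a carbonic anhydrase relative on chromosome 4 without the enzyme's activity, also fell. No gene with a position-checked name rose past the threshold.

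Cftr (chromosome 6, 18170687 to 18322768, GRCm38) had rescaled values of 737, 1107, 706 and 790 in WT replicates 5680, 5842, 6684 and 6752. In HO replicates 5806, 5837, 6683 and 6747 it had 284, 291, 283 and 275. The means were 835 ± 185 (SD, n = 4) and 283 ± 6.61 (n = 4), a 2.95-fold lower level in HO, with a log2 change of -1.53 (SE 0.13, limma adjusted p 1.02e-05). Lower values in 4 of 4 HO libraries go with the genotype labels.

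Aass (chromosome 6, 23072173 to 23132986) averaged 382 ± 13.0 (SD, n = 4) in WT and 162 ± 6.58 (n = 4) in HO, a log2 change of -1.23 (SE 0.12, limma adjusted p 5.73e-05). Cttnbp2 (chromosome 6, 18366478 to 18514843) averaged 635 ± 199 and 305 ± 46.8, with a log2 change of -1.02 (SE 0.17, limma adjusted p 0.0336). Car8 (chromosome 4, 8143362 to 8239041) averaged 2378 ± 294 and 1544 ± 137, with a log2 change of -0.62 (SE 0.11, limma adjusted p 0.0300). The groups did not overlap for any of these. On the deposited scale, relative to its median, the log2 changes were -1.03 for Cttnbp2 and -0.63 for Car8, but neither passed, with limma adjusted p of 0.0560 and 0.620.

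Of 15726 tested features 24 passed, 5 higher and 19 lower in HO, against 11 (5 higher and 6 lower) on the deposited scale, of which 7 are shared. Of the 24, 4 have position-checked names. The number rests on single libraries: without WT replicate 6752 it was 3, and without WT replicate 5842 it was 4. Features deposited under the names Mapk14 (log2 change 1.27), Slc26a8 (1.19), Mast1 (0.68), Synm (0.67) and Vmn2r78 (0.67) were higher. Those deposited as Tmbim6 (-1.46), Gucy2f (-1.38), Dnah1 (-1.37), Mmp3 (-1.34), Ddx24 (-0.89), Gzf1 (-0.86), Eltd1 (-0.85), Slc44a4 (-0.81) and Ehmt2 (-0.76) were lower.

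Several position-checked genes named by the rule did not pass. Tspan12, a tetraspanin of Norrin signalling, had a log2 change of -0.44, Impdh1, of guanine nucleotide synthesis, -0.42, and Met, the receptor of hepatocyte growth factor, -0.41, with limma adjusted p of 0.118 to 0.121. For Ddx58, the viral RNA sensor RIG-I, it was -0.38, for Gng11, a G protein subunit, -0.48 and for Tomm5, of mitochondrial import, -0.53. Among rises the kinase Pdk4, which holds back pyruvate oxidation, had the largest change, 1.11, with an adjusted p of 0.382. Ppp1r3a, Spag8, Thsd7a, Ptprz1, Coro2a, Proser2, Anks6, Bach2it1 and Bambi did not pass either, with adjusted p from 0.334 to 0.609.

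The second comparison asked the same of libraries labelled lung. Cftr fell in HO here too. Gm15592 and Gm15595, predicted transcripts within the span of Cftr, fell with it. They are outside the symbol rule and were chosen after their values were seen. No other gene with a position-checked name passed.

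Cftr had rescaled values of 2842, 3747, 3773, 2916 and 3047 in WT replicates 5680, 5839, 5842, 6684 and 6752, and of 172, 142 and 107 in HO replicates 5678, 5806 and 6683. The means were 3265 ± 458 (SD, n = 5) and 141 ± 32.4 (n = 3), 23.2-fold lower in HO, with a log2 change of -4.54 (SE 0.17, limma adjusted p 1.58e-11). Gm15592 (18270136 to 18289048) averaged 37.8 ± 16.3 (n = 5) in WT and 2.94 ± 1.28 (n = 3) in HO, with a limma adjusted p of 0.0033. Gm15595 (18294271 to 18295231) averaged 22.9 ± 6.28 (n = 5) in WT and had no read in the HO libraries, with a limma adjusted p of 0.00238. As the strand setting is not known, reads of Cftr and of these models within it were not separable.

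**Figure D3:**
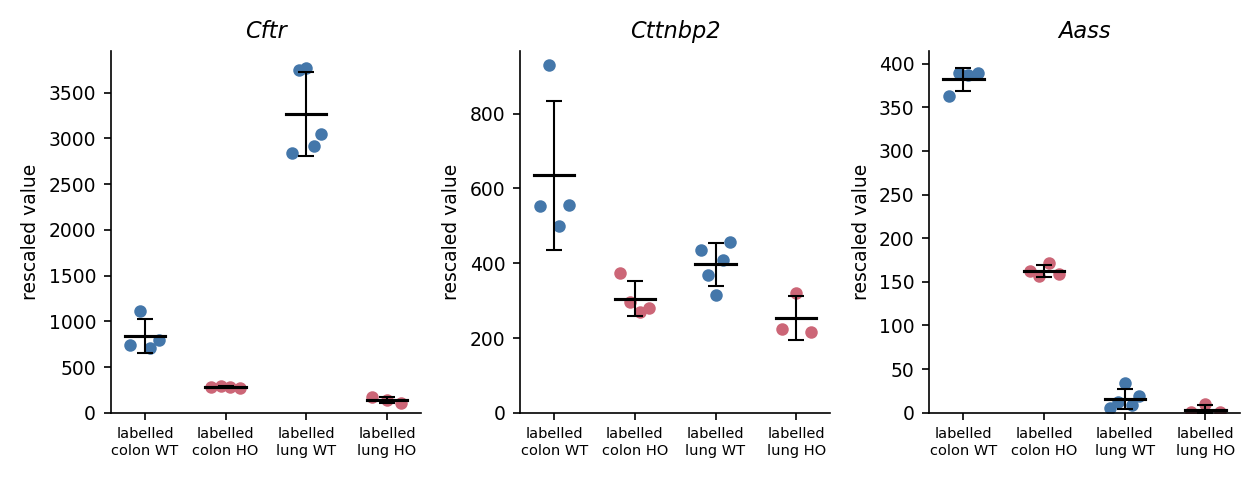
Rescaled values of Cftr, Cttnbp2 and Aass per library (points) with the group mean (bar) and SD (error, drawn down to 0 where it exceeds the mean). Cftr averaged 835 and 283 in WT and HO labelled colon, and 3265 and 141 in WT and HO labelled lung.

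Of 13908 tested features 12 passed, 1 higher and 11 lower in HO, against 10 (6 higher and 4 lower) on the deposited scale, of which 4 are shared. On the deposited scale the median log2 change of all features was 0.56, against 0.03 on the rescaled scale. The 6 higher and 4 lower are counted by sign alone, not relative to that median. Of the 12, 3 have position-checked names. With Cftr and the models within it left out 9 remained, and 3 of 56 splits of the libraries gave as many, the real one included. Without WT replicate 6752, whose scale differed, 23 passed, and without HO replicate 5806 it was 4. The feature deposited under the name Ighv1-17-1 averaged 1.69 in WT, near the floor, and 52.0 ± 47.2 (n = 3) in HO. Those deposited as Mir370 (log2 change -1.62), Cdhr5 (-1.60), Deaf1 (-1.53), Dnah5 (-1.47), C1qtnf3 (-1.33), Rtl1 (-1.27) and Nup133 (-1.03) were lower.

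Several checked genes named by the rule did not pass here either. Galnt12, which starts the O-glycans of mucins, had a log2 change of -0.98 (limma adjusted p 0.152), Slc35a1, the sialic acid transporter of the Golgi, -0.81 (0.251), and Spink4 -0.80 (0.417). Decr1, of fatty acid oxidation, had -0.61 (0.258) and Car9, a carbonic anhydrase induced by hypoxia, -0.77 (0.323). Lsm8 (-0.95), Fam3c (-0.87), Cttnbp2 (-0.66) and Tfpi2 (-1.04) did not pass, with adjusted p from 0.198 to 0.457. The smallest p among rises belonged to Tmem64, at a log2 change of 0.54 (0.417). Tmeff1, Osgin2, Trp53inp1, Manea, Plag1, Irf5, Nr4a3, Tex10 and Celf2 followed, up to an adjusted p of 0.745.

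The third comparison asked whether the HO effect differs between the labelled tissues. Cftr was the gene with a position-checked name that passed, and it fell by more in libraries labelled lung. The difference of its log2 changes was -3.01 (SE 0.22, limma adjusted p 2.06e-08), with lower values in 4 of 4 and 3 of 3 HO libraries. Features deposited as Cdhr5 (-2.63, SE 0.43, limma adjusted p 0.0475) and Dnah5 (-1.68, SE 0.28, limma adjusted p 0.0306) also passed, which makes 3 of 12994, all negative. On the deposited scale 1 passed, and the median of all features there was 0.48, against 0.01 on the rescaled scale. At least 2 features besides Cftr were also called in 6 of 100 drawn splits, the real one included. Of checked genes on the negative side, Spink4 (-1.17, adjusted p 0.573), Decr1 (-0.54), Fam3c (-0.70) and Proser2 (-0.83) were among those with the smallest p and did not pass. On the positive side Tmeff1 (0.83), Fam171a1 (0.65), Tmem64 (0.62), Manea (0.72), Clvs1 (1.64) and Met (0.65) did not pass, up to an adjusted p of 0.827.

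Gene lists fixed before the data were examined were tested in each tissue. In libraries labelled colon 1 of 49 lists passed, the genes beside Cftr, which does not hold Cftr itself and whose 29 tested members all have position-checked names. Of these, 19 were lower and 10 higher in HO, with a median log2 change of -0.15. Aass and Cttnbp2 passed over all features, and 5 members passed when adjusted over the list alone. The camera adjusted p from limma was 0.00191 at the preset correlation and 0.669 with the correlation estimated. The adjusted p of fry, another test, was 0.186. Over 49 lists the call thus holds neither with the correlation estimated nor with fry. As the only list with at least 4 position-checked members, tested alone after the data had been seen, it had 0.0273 with the correlation estimated and 0.00381 with fry. Camera still compared it with all tested features, and fry with no change. The median log2 change labelled colon was 0.01 over all features but -0.08 over position-checked names, so that part of the fall may be common to checked names. In libraries labelled lung 0 of 49 lists passed by camera, against 4 at an unadjusted p under 0.05, and 0 by fry. The genes beside Cftr had 16 members lower and 10 higher of 26 there, 0 past the threshold over all features and 4 adjusted over the list alone, with a limma adjusted p of 0.155. Their median log2 change was -0.03, against -0.09 over position-checked names and 0.03 over all features. For 29 lists labelled colon and 30 labelled lung no tested member has a position-checked name. Every other list except the genes beside Cftr has at most 2 such members, as with 2 of 21 for ion and fluid transport labelled colon. For all lists but the genes beside Cftr it is therefore not established that the tests measure the genes the lists were made of.

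**Figure D4:**
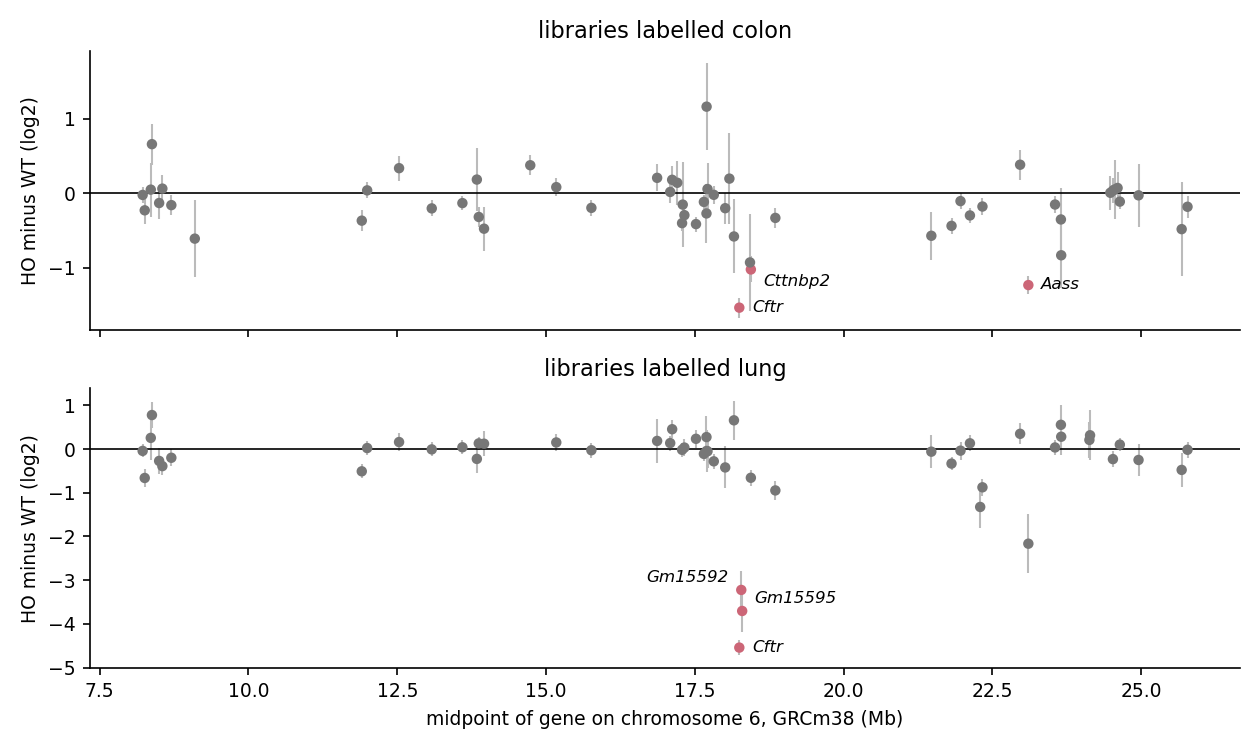
Log2 change in HO against WT (points, with SE) of tested genes within 10 Mb of Cftr on chromosome 6, by position, for each labelled tissue. Red marks genes past the threshold: Cftr, Cttnbp2 and Aass labelled colon, and Cftr, Gm15592 and Gm15595 labelled lung.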

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

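The tests on a shared segment and on overlapping gene models near Cftr, and the counts of other splits, were chosen only after the results had been seen.

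Single libraries far from the others of their group were sought in 110 groups of values, and 6 were found; chance gives about 1 in 20. In libraries labelled colon, WT replicate 5680 had 2429899 recovered reads, 2.43 in units of 1000000, against 3.34 to 3.49 in the other WT libraries. The same library had the lowest Aass, 363 against 387 to 390, and the highest Coro2a, 160 against 117 to 122. WT replicate 5842 had 932 for Cttnbp2 against 499 to 556. WT replicate 6752 had 173 for the feature named Dnah1 against 229 to 236, and 62.3 for the feature named Mapk14 against 93.0 to 97.5. Each of these named features kept its WT and HO groups apart except Coro2a, which did not pass. Without WT replicate 6752 labelled colon 3 features passed in place of 24, without WT replicate 5842 4 and without WT replicate 5680 6.

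A difference of the HO effect between the labelled tissues, by the test of the difference itself, was found for Cftr (-3.01) and for the features named Cdhr5 (-2.63) and Dnah5 (-1.68). Splits were drawn in each tissue apart, so that an animal number found in both tissues could be given both genotypes, unlike in the real grouping. Of 100 drawn splits of the libraries within tissue, 4 gave at least 3 features, the real one included, and the highest of the others gave 13. A number that far above the real one points to a structure of the samples, which was not tested. With Cftr left out, 6 of 100 gave at least the 2 other features, so that chance is not excluded for Cdhr5 and Dnah5 by these splits. Of the others among them, 1 keeps the real lung HO group and so holds the real effect there, and the 2 highest share the grouping of lung WT 5842 with lung HO 5806 and 6683. With edgeR the adjusted p for Cdhr5 was 0.146, and over its alternatives it ran from 0.000185 to 0.363.

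Called genes near Cftr were lower in HO, but a count of lower genes alone did not differ detectably between the genes around it and other checked genes. Within 10 Mb, with models that overlap Cftr left out, 10 of 56 were lower at an unadjusted p under 0.05 labelled colon against 39 of 379 other checked genes (Fisher's exact p 0.111), and 8 of 50 against 35 of 360 labelled lung (Fisher's exact p 0.214). Higher at that p were 2 of 56 against 4 of 379 labelled colon, and 2 of 50 against 5 of 360 labelled lung. Changes in either direction, counted together, were not tested. The median log2 change of the genes around Cftr was -0.14 against -0.07 labelled colon and -0.02 against -0.10 labelled lung. The fixed list of genes beside Cftr, compared with all tested features, was lower labelled colon (camera adjusted p from limma 0.00191, and 0.669 with the correlation estimated). The called neighbours were also lower labelled lung without passing, Aass at -2.16 (limma adjusted p 0.510), near the floor there, and Cttnbp2 at -0.66 (0.363).

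Of the 4 called features near Cftr besides Cftr itself, 2, Aass and Cttnbp2, lie outside its annotated span. Reads of Cftr counted in models that overlap it would not explain these 2, but stay open for Gm15592 and Gm15595. Whether reads of Cftr beyond its annotated span were counted in Cttnbp2 was not tested. A chromosome segment carried along with the mutation may bring other alleles of neighbouring genes, and effects may then be shared by the tissues. Effects of the mutation itself may be shared as well. Over 47 genes the HO effects correlated between the tissues with a Spearman rho of 0.222, where random sets of checked genes had a median of 0.132 (permutation p 0.282). Mutation and any such segment go together in the genotype, so that this correlation cannot tell them apart. Genes are also not independent replicates.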

How the results depend on the processing

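Limiting tests and lists to position-checked names was chosen only after the data had been seen. Labelled colon, 24 features passed. Without a filter 96 passed, on the deposited scale 11, without trend and robust estimation 1, with library weights 43, at an adjusted p under 0.1 42 and with DESeq2 100. From a fit of all 16 libraries 3 passed, and 4 with the animal number as a block. Over position-checked names alone 9 passed, Tspan12, Impdh1, Met, Ddx58 and Gng11 in addition, and 4 of these names on the deposited scale. Equal totals gave 19 (7 higher and 12 lower) and edgeR 26. Leaving out each replicate gave 3 to 30, with 6 without WT replicate 5680, 4 without WT 5842, 3 without WT 6752 and 12 without HO 6683.

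Labelled lung, 12 passed. Without a filter 45 passed, with a filter of 50 7, without trend and robust estimation 2, with library weights 60, with DESeq2 40, with the leading digit as a covariate 23, over position-checked names 4, Decr1 in addition, and on the deposited scale over these 3. Leaving out each replicate gave 4 to 23, with 6 without WT 5839, 6 without WT 5842, 23 without WT 6752, 4 without HO 5806 and 6 without HO 6683. For the genotype by tissue term 3 passed, against 1 on the deposited scale, 1 without trend and robust estimation, 13 with DESeq2, 5 with the leading digit, 1 with the Y-linked mean, 1 over position-checked names on either scale, 3 with the block and 1 to 4 without each replicate. It was 1 without WT 5842, WT 6684, HO 5806 or HO 6683 labelled colon, and without WT 5839, WT 6752, HO 5806 or HO 6683 labelled lung.

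For lists labelled colon, 1 passed, against 0 with an estimated correlation, 0 with fry and 1 to 3 without each replicate (3 without WT 5680 or HO 5806). Tested as the only list with enough position-checked members, the genes beside Cftr had a p of 0.0273 with an estimated correlation and 0.00381 with fry. The background of camera was still all tested features, not the position-checked names. For lists labelled lung, 0 passed, against 2 on the deposited scale (ionocyte and Y-linked), 1 with position-checked members, 1 with these on the deposited scale and 0 to 1 without each replicate (1 without HO 5806). With position-checked members this was the genes beside Cftr, at a limma p of 0.00589, against 0.0754 with an estimated correlation and 0.0536 with fry, where 0 passed. The ionocyte list holds Cftr, its only position-checked member and the only 1 called on the rescaled scale. Of its 8 tested members 4 were lower and 4 higher there. The 4 Y-linked features had an estimated correlation of 0.997, far above the preset 0.01. The genes beside Cftr had the same 26 tested members and the same limma p among all lists labelled lung. Fewer tests therefore account for that call at the preset correlation. For single features fewer tests explain part of the change over position-checked names, and otherwise the cause was not tested.

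None of 78 results on single genes reversed, with the deposited scale read relative to its median. Of 32 that passed, 3 passed under every alternative run: Cftr labelled lung, Cftr in the genotype by tissue term and Gm15595 labelled lung. Cftr labelled colon failed under 1 of 26, at an adjusted p of 0.0690, Aass under 2, Cttnbp2 under 8 and Car8 under 9. Of calls, edgeR shared 23 of 24 labelled colon and 11 of 12 labelled lung, and DESeq2 24 and 12. Small changes can be missed: in simulated data 45.7% of features changed 2-fold were called labelled colon and 31.9% labelled lung. Whether depth, spread or the number of replicates limits this was not tested.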

Other observations

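Every test of an explanation in this part, and the counts of other splits, were chosen only after the result they test had been seen.

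Other splits of the same libraries were counted with the same test. Labelled colon, 1 of 35 splits gave as many features as the real one, which is the real one itself with 24, and the highest other split gave 1. That share, 0.0286, is the smallest that 35 splits can give. It argues against chance on the rescaled scale alone, which was made the main one after it was seen to give more features. Splits were not counted on the deposited scale. With Cftr and the models that overlap it left out, the real split gave 23 and the count stayed at 1 of 35. Labelled lung, 1 of 56 gave as many, the real one with 12, and the highest other split gave 11. With Cftr and the models that overlap it left out, the real split gave 9 and 3 of 56 gave as many, so that chance is not excluded for the remaining features. For lists labelled colon, 14 of 35 splits gave at least the 1 list of the real split and the highest other gave 4, so that chance is not excluded. For lists labelled lung the real split gave 0, so that 56 of 56 gave as many and there is nothing to test, and the highest other gave 3.

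Names and reads went apart outside the position-checked stretches. Too few reads per library would lower genes on every chromosome alike, and counting on the opposite strand would not follow position either. Both are argued against by other named protein-coding genes, which set no stretch and passed 35.7 points more often inside (Fisher's exact p 2.06e-38). A candidate explanation is that positions of the annotation and of the alignment drift apart along chromosomes, as with annotation and reads of different assemblies. Genes held out of the search passed 39.6 points more often inside refitted stretches (Fisher's exact p 6.66e-05), which were shorter than those used, and the assembly itself was not established. Genes side by side are not independent replicates, so that either Fisher's exact p may be too small.

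Markers with position-checked names went against the tissue labels, 6 of 6 of them. Names out of place would send markers either way, which an exact two-sided binomial p of 0.0312 argues against. That p is the smallest that 6 markers can give. It takes the markers as independent, although all lie in the stretches of chromosomes 4 and 6. Gut tissue mixed into libraries labelled lung would leave markers of lung there, but their median level was 3.12% of that in libraries labelled colon. Exchanged tissue labels, at deposition or before, may account for 6 of 6. No library was moved, and no biological explanation was tested.

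Between the labelled tissues 263 position-checked names with a deposited value of at least 200 in a library were compared. Of these 148 did not overlap, 63 higher labelled lung and 85 higher labelled colon, where chance gives 0.0155%. Mitochondrial names took 5.80% to 7.28% of the deposited total labelled colon and 15.95% to 22.8% labelled lung, with 9.48% in WT replicate 6752, the library on another scale.

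Features deposited under the Y-linked names Ddx3y, Eif2s3y, Kdm5d and Uty had deposited values of at least 856 in 1 colon WT, 2 colon HO, 2 lung WT and 2 lung HO libraries as labelled, and of at most 7 in the others. Their level went together in 6 of 6 animal numbers with both tissues. These names were not position-checked.

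Called features lay near one another by the positions of their names. Labelled colon, 7 of 23 with a position had another within 1 Mb, where random draws of tested features gave a mean of 0.851 and at most 8 (permutation p 0.0005). Labelled lung, 7 of 12 did, where random draws gave a mean of 0.222 and at most 5 (permutation p 0.0001, the smallest that 10000 draws can give). With Cftr and the models that overlap it left out, the numbers were 5 of 22 labelled colon (permutation p 0.0055) and 4 of 9 labelled lung (permutation p 0.0013). No explanation was weighed for this.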
